A study of Mus musculus with 9 samples.

How the data were processed

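Chromatin immunoprecipitation with antibodies to E2A or HEB, and an input control, was sequenced from mouse DN3, CD73- and CD73+ cells, 9 libraries with 1 per group. Per the labels' protocols, DN3 cells were harvested at day 7 of culture, transduced cells were sorted 3 days later, and chromatin was fixed for 10 min in 1% formaldehyde. Per the submitters' processing notes, the tools were Bowtie, HOMER and MACS 1.4.2 with genome build mm10. Duplicate samples were joined by the authors before peak calling. The 6 files used are peak lists, and the deposited score of each peak is the authors' -10 log10 of the MACS p-value, at least 50 in these files, with ties at 3100. Scores were not changed and serve only to describe, rank and filter peaks within a list. The files carry no read depth, and no read data were used here. Lists were assigned to groups by the cell and antibody names they carry, and 0 were left unmatched.

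The comparisons, their tests, the gene lists and the rule for named genes were set before the data were examined. Alternatives, closing tests and genes chosen later are named as such where they appear. Peaks on chromosomes 1 to 19, X and Y were used as deposited. The share of the first list with an overlap of at least 1 bp in the second was given with its 95% Wilson interval, which covers counting error only. For a permutation p, the second list was placed at random 1000 times within its chromosomes with widths kept, 1-sided and doubled, so that the smallest p is 0.001998. It was adjusted by the Benjamini-Hochberg method over 9 comparisons. This test asks whether 2 lists overlap beyond position alone. It compares these libraries, not conditions. Each group has 1 pooled list, so no p against replicate error was computed.

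The reference was a table of 49997 mouse genes of the same build, of which 21907 were used. It gives spans but no strand, transcription start site or exon, and no genome sequence was used. The 20 fixed gene lists hold 278 symbols, matched to 274 genes, with markers of B, myeloid, erythroid, stromal and liver cells among them. A gene was counted if a peak lay in its span or within 10 kb on either side. The count was ranked among 10000 random lists of the same size, matched on gene span in 10 bins, and called beyond chance in the top or bottom 2.5%, with Benjamini-Hochberg adjustment over the 20 lists. Changes between stages were ranked in the same way, so that the random lists carry the overall difference in peak number. Percentiles and their p describe gene sets within these libraries only. Regions across stages are peaks of a factor merged where they touch, and a strong region holds a peak scoring at least 100.

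Named genes follow a rule set in advance. It takes up to 4 members of each fixed list with the highest peak and up to 3 with peaks in some stages only. It adds the 3 highest peaks of each list, the 5 highest regions of each factor and stage pattern, and a set of regulators and markers named whatever their values, such as Id3, Tcf7, Nt5e, Ptcra, Rag1, Sox13, Egr2 and Gata3. Ties in score among these peaks and regions were taken in order of position. The rule asked for the nearest start site, and the nearest span of a protein-coding gene was used in its place. Some genes that the rule names are not reported here, though they count in the totals of their lists.

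Alternatives fixed in advance were a score of at least 100, equal list lengths of 9407 peaks, reciprocal overlap of 50%, midpoints within 200 bp, leaving out peaks wider than 3000 bp, and all sequences in the files. Added after the data were seen were the top 1000 peaks per list, the first list alone at a score of at least 100, random placement within classes of distance to a gene end, peaks that overlap another list, the nearest gene span, peaks within 5 kb of a gene end, random gene lists matched also on a peak in the first stage, merged regions with the CD73+ lists of E2A and HEB exchanged, and the share of peaks within 1 kb or 2500 bp of either gene end. The planned searches for E-box sequences and 16 other motifs and the start site distances were not run, since they need sequence and strand. The overlap and gene list methods were tested on simulated data. With no shared sites 0 of 20 runs had a p under 0.05, and with 2% of sites planted 5 of 5 did. The simulated peaks were placed at random in the same way as in the test, so uneven background was not simulated. Gene lists of random members were called above chance in 3.5% of 200 simulations, and lists with 10 of 16 members planted in all of them. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.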

Results

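The series measured where 2 E proteins sat on the genome of mouse thymocyte precursors, by chromatin immunoprecipitation and sequencing. E2A and HEB, encoded by Tcf3 and Tcf12, are basic helix-loop-helix factors that bind DNA as dimers and are held in check by Id proteins. Per the labels, Rag2-deficient fetal liver progenitors were grown to the DN3 stage, at which thymocytes normally rearrange their T cell receptor genes. Some of these cells then received the genes of KN6, a gamma-delta T cell receptor, and were cultured for 3 days on OP9-DL1, a stromal line that expresses a Notch ligand. The transduced cells were sorted into CD73- cells, which per the labels could still take the alpha-beta fate, and CD73+ cells, which were committed to the gamma-delta fate. Each of the 3 stages had 1 input, 1 E2A and 1 HEB library, 9 in all, and the deposited peak lists number 6. Duplicates were pooled by the authors before peaks were called, so no value below has a replicate error. Read depth is not stated in the peak lists and is unknown here. A gene described as without a peak had none called, which is not evidence that the factor was absent.

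On the 21 main chromosomes the E2A lists held 12357 peaks in DN3 cells, 12434 in CD73- cells and 23205 in CD73+ cells, and the HEB lists held 11619, 9407 and 10194. Peaks with a score of at least 100, called strong here, numbered 5011, 1093 and 1629 for E2A and 3567, 1348 and 2458 for HEB. The score is the authors' -10 log10 of the p-value of a peak, and it ranks peaks within a list only. Thus 40.6% of DN3 E2A peaks were strong, against 7.02% of CD73+ E2A peaks. Of peaks scoring under 100, from 14.2% (CD73+ E2A) to 45.6% (DN3 HEB) overlapped a peak of any other list. A single peak close to the minimum score of 50 is therefore weak evidence of a site. The highest score of the DN3 E2A list, 3216, belonged to a peak 3895 bp from Trim80. Of its 30 peaks at 3100 or more, those near Btg2, an antiproliferative gene, and in Edem3 were named from ties at 3100. Whether a score above 3100 marks a stronger peak than these ties is not known here. The highest DN3 HEB score, 3213, belonged to a peak on chromosome 4 at 40874617 to 40877554, 22101 bp from B4galt1, a galactosyltransferase gene. The highest CD73- E2A score, 3156, belonged to a peak nearest Ly6c2, and Ndufaf6 held a peak of 3100 in the CD73- and CD73+ HEB lists. In each CD73- or CD73+ list 5 to 9 peaks scored 3100 or more, and those named were taken from ties by position. The others so named lay on chromosome 2 near 98.7 Mb, over 1 Mb from the nearest protein-coding gene, Lrrc4c. Peaks stood there in all 6 lists, and possible regions of high background were not removed. Median peak width was 617 bp and 721 bp in the DN3 E2A and HEB lists, and 149 bp to 181 bp in the other 4.

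**Figure D1:**
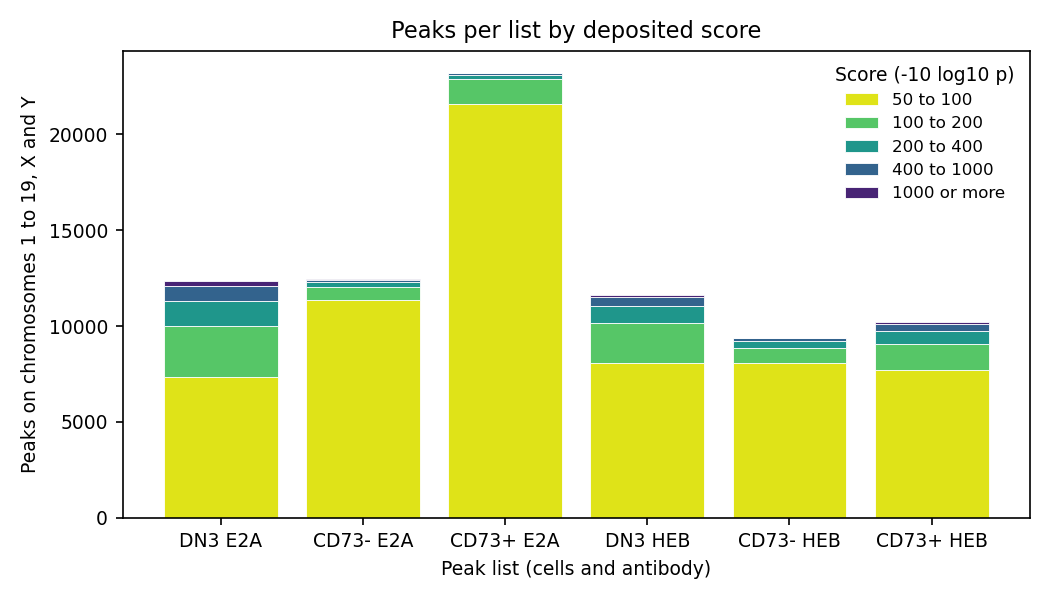
Number of peaks (y axis) in each of the 6 lists (x axis), with bars divided by peak score (-10 log10 p). The CD73+ E2A list is the longest at 23205 peaks, and the DN3 E2A list has the most peaks with a score of at least 100, 5011.

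The first question was how far HEB peaks coincide with E2A peaks within a stage. Genes named below were picked by a fixed rule, mostly as the highest-scoring members of their lists, and do not sample the genome. For each gene the highest peak in its span or within 10 kb is given, with positions in mouse build mm10. In DN3 cells Notch3, a receptor that acts in early thymocytes, had peaks of 2272 for E2A and 1591 for HEB, the E2A peak at chromosome 17, 32163704 to 32165093. Trac, the alpha chain constant region, had peaks of 2804 and 1311, and Ccnd3, the cyclin that drives pre-T cell division, of 2499 and 3002. E2f2, a cell cycle transcription factor, had 2416 and 1707, and Selplg, a selectin ligand used in homing, had 2286.5 and 1577. Of 11619 HEB peaks, 5339 overlapped an E2A peak, 46.0% (95% Wilson interval 45.0% to 46.9%). Random placement of the E2A list gave 0.764%, a 60.1-fold difference (permutation p = 0.002, two-sided, the smallest that 1000 placements allow). Of strong HEB peaks, 85.1% overlapped an E2A peak. Among DN3 HEB peaks scoring at least 1000, 98.2% did so. Among DN3 E2A peaks at that level, 99.7% overlapped a HEB peak.

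In CD73- cells, Ccnd3 had peaks of 1486 for E2A and 2466 for HEB, Selplg of 811 and 1116, and Il6ra, the interleukin 6 receptor, of 657 and 607. Sox4, a factor of early T and gamma-delta cells, had 475 and 442, and Trac had 577 and 1074. Of 9407 HEB peaks, 2084 overlapped an E2A peak, 22.2% (21.3% to 23.0%), 116-fold above random placement at 0.191% (permutation p = 0.002). The random share depends on peak width and list length, so these fold values cannot be compared between lists or stages. Of strong HEB peaks 74.0% did so.

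In CD73+ cells several of the named genes with high HEB peaks had no E2A peak. Cd27, a costimulatory receptor, had 1128 for HEB and no E2A peak, Ccr9, a thymic homing receptor, had 1079 and none, and Trbc2, a beta chain constant region, had 1026 and none. Nr4a1, an orphan receptor gene induced by antigen receptor signals, had 751 and none. Trac had 3063 for HEB and 319.9 for E2A, and E2f2 had 2721 and 248. Of 10194 HEB peaks, 1511 overlapped an E2A peak, 14.8% (14.1% to 15.5%), 38.7-fold above random placement at 0.383% (permutation p = 0.002). Of 2458 strong CD73+ HEB peaks, 31.8% overlapped a CD73+ E2A peak, whereas 85.2% overlapped a DN3 E2A peak and 78.9% a DN3 HEB peak. Of all CD73+ E2A peaks 16.8% overlapped a peak of any other list, against 53.1% of CD73+ HEB peaks. The E2A and HEB lists of a stage share 1 input library, so part of their overlap may come from it. With overlap required to span 50% of both peaks, the shares were 41.2% in DN3, 16.3% in CD73- and 8.94% in CD73+ cells.

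The next question was which DN3 sites of E2A still had a called peak in the transduced cells. No cells transduced without the receptor or cultured for the same time are among the samples. Effects of the receptor therefore cannot be told apart from those of transduction, added culture and sorting. In CD73- cells, E2A peaks were still called at Notch3 (505), Notch1 (347), Ikzf3, a lymphoid zinc finger factor (396), and Arpp21, a thymocyte RNA regulator (303). None was called at Rag1, the recombinase gene, whose DN3 peak of 552 lay 710 bp outside the gene on chromosome 2 at 101650243 to 101651015. Tcf7, which encodes the T cell factor TCF-1, had a DN3 peak of 401 and Cd27 of 935, and neither had a CD73- E2A peak. Ptcra, the pre-T cell receptor alpha chain, had a DN3 peak of 112 at chromosome 17, 46767742 to 46768369, and none later. Of 12357 DN3 E2A peaks, 1610 overlapped a CD73- E2A peak, 13.0% (12.4% to 13.6%), 30.5-fold above random placement (permutation p = 0.002). For strong DN3 peaks the share was 24.3%, and with overlap required over 50% of both peaks it was 1.66%, a share that the narrower CD73- peaks limit by construction.

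In the CD73+ list labelled E2A fewer of these sites had a peak, whereas 51.3% of strong DN3 E2A peaks overlapped the CD73+ list labelled HEB. Notch1 had no CD73+ E2A peak, and Notch3 had a peak of 78.2. Lck, the proximal kinase of the T cell receptor, and Lat, its adaptor, had DN3 E2A peaks of 517 and 627 and no CD73+ E2A peak. Bcl2l1, a survival gene, had 808 in DN3 and none in CD73+ cells. Of the gamma-delta factor genes, Sox4 had a CD73+ E2A peak, at 273, and Sox13 had none. Of the DN3 E2A peaks, 1145 overlapped a CD73+ E2A peak, 9.27% (8.77% to 9.79%), 12.1-fold above random placement (permutation p = 0.002), and 15.2% of strong DN3 peaks did so. With overlap over 50% of both peaks the share was 0.696%, again limited by the narrower peaks. Of 289 DN3 E2A peaks scoring at least 1000, 91.0% overlapped a CD73- E2A peak and 61.2% a CD73+ E2A peak. A peak of the CD73+ list labelled HEB overlapped 93.1% of them. Between the sorted populations, 1919 of 12434 CD73- E2A peaks overlapped a CD73+ E2A peak, 15.4% (14.8% to 16.1%), 46.8-fold above random placement (permutation p = 0.002). Of strong CD73- peaks 61.1% did so.

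The same question was asked of HEB. Trac, Arpp21, Ikzf3 and Notch3 had HEB peaks at all 3 stages, with CD73+ scores of 3063, 1031, 1161 and 952. Rag1 had HEB peaks of 127, 70.6 and 169 in DN3, CD73- and CD73+ cells. Tcf7 had HEB peaks in DN3 and CD73+ cells, 205 and 136. The CD73+ peak, at chromosome 11, 52292925 to 52293311, lay within the DN3 E2A peak there. Ptcra had a DN3 HEB peak of 73.7 and Cd4, the coreceptor gene, of 114, and neither had one in CD73- or CD73+ cells. Of 11619 DN3 HEB peaks, 2256 overlapped a CD73- HEB peak, 19.4% (18.7% to 20.1%), and 3157 a CD73+ HEB peak, 27.2% (26.4% to 28.0%). These shares were 51.9-fold and 62.7-fold above random placement (permutation p = 0.002 for each). Among strong DN3 HEB peaks they were 44.5% and 57.6%. Requiring 50% of both peaks gave 0.895% and 4.43%, limited by width in the same way and, for CD73- cells, below the E2A value. Across factors, 27.9% of DN3 E2A peaks overlapped a CD73+ HEB peak and 14.2% of DN3 HEB peaks a CD73+ E2A peak, so which factor shows the larger share in CD73+ cells depends on their E2A and HEB labels, which the data did not settle. Between CD73- and CD73+ cells, 2338 of 9407 HEB peaks were shared, 24.9% (24.0% to 25.7%), 133-fold above random placement (permutation p = 0.002), and 78.1% of strong ones were. With the CD73+ lists exchanged, 18.1% of all and 54.3% of strong CD73- HEB peaks were shared. For CD73- E2A peaks the exchanged shares were 15.5% and 77.8%.

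**Figure D2:**
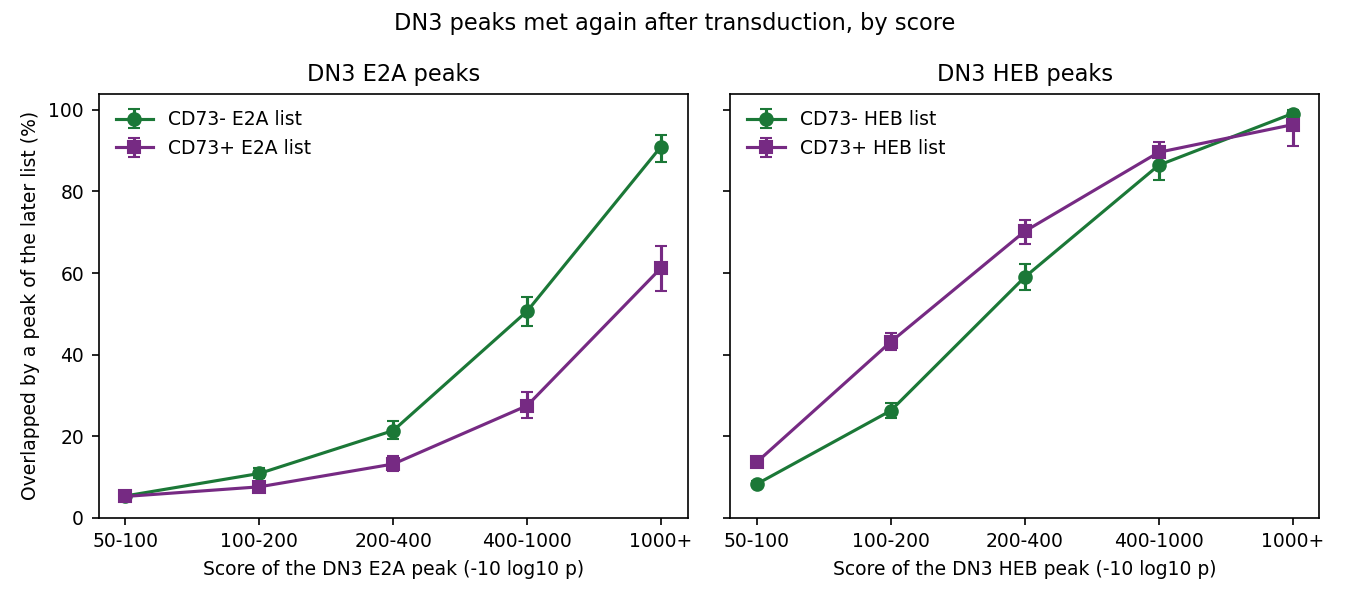
Percent of DN3 peaks overlapping a peak of the same factor in CD73- or CD73+ cells (y axis), by class of DN3 peak score (x axis, -10 log10 p), with 95% Wilson intervals. By the CD73+ labels, which are not settled, the share in CD73+ cells runs from 13.7% to 96.4% for HEB and from 5.24% to 61.2% for E2A.

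Merged across stages, strong E2A regions numbered 6437, of which 3645 (56.6%) had a peak in DN3 cells only and 693 (10.8%) at all 3 stages. The DN3 lists hold the most strong peaks, so this threshold favours DN3-only regions. Of all 43624 E2A regions, 47.6% were CD73+ only, 23.8% DN3 only and 1.77% at all 3 stages. Strong HEB regions numbered 4681, of which 1227 (26.2%) were DN3 only, 1452 (31.0%) were at all stages, and 1000 (21.4%) had peaks in DN3 and CD73+ but not CD73- cells. Of all 24364 HEB regions, 32.0% were DN3 only, 24.8% CD73+ only and 6.56% at all stages. These shares rest on the CD73+ labels, which are not settled. With the CD73+ lists exchanged, a version added later, 39.2% of 5908 strong E2A regions were DN3 only and 20.0% at all stages, and of 4945 strong HEB regions 37.5% were DN3 only, 16.6% at all stages and 3.34% in DN3 and CD73+ but not CD73- cells. The highest DN3-only E2A regions lay near Hsdl1 (2257) and near Xbp1 (1913), a gene of the unfolded protein response. The Xbp1 region, on chromosome 11 at 5499885 to 5501723, was also the highest DN3-only HEB region, at 1039. The highest CD73+-only HEB region, at 489.6, lay 16556 bp from Icos, a T cell costimulatory receptor, on chromosome 1 at 61016567 to 61017191. Another, at 408, lay 25885 bp from Ifngr1, the interferon gamma receptor, and Ctnnd1 held a region of 455. CD73+-only E2A regions were highest in Cartpt (784.9) and Ppargc1a (670.3). Strong peaks of the CD73+ E2A list differed from those of the other lists. Of them 51.3% overlapped a peak of any other list, against 84.3% to 93.8% elsewhere. Their median width was 143 bp, below the 175 bp of that list's peaks scoring under 100, whereas strong peaks were the wider ones in every other list. Regions with peaks in both sorted populations and none in DN3 cells made up 3.68% of strong E2A regions, such as 1 in Ano2 (292 and 534). They made up 3.10% of strong HEB regions, such as 1 in Ccdc146 (62.2 and 538). With the CD73+ lists exchanged, these shares were 1.71% for E2A and 2.67% for HEB.

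A set of 20 gene lists tested whether genes of a given function carried peaks more often than random genes of like span. In DN3 cells, E2A peaks lay in or within 10 kb of 16 of 17 genes of the pre-TCR and alpha-beta lineage, against 4.54 in random lists. They lay at 15 of 19 TCR complex and proximal signalling genes (6.04 at random), 14 of 18 T lineage transcription factors (7.21) and 14 of 18 cytokine receptor and JAK-STAT genes (5.24). They also lay at 12 of 15 chemokine receptor and homing genes (3.44), including Cxcr4 (703) and Cxcr5 (811.5). The TCR signal response list, genes induced by antigen receptor signals, had 12 of 20 (4.60), including Egr1 (346), Nr4a1 (414) and Dusp2 (386). HEB peaks lay at 13, 16, 16, 13, 12 and 13 members of these 6 lists. Of the 20 lists, 12 were above chance for each factor in DN3 cells, that is, within the top 2.5% of random lists. Of these, 11 for E2A and 10 for HEB had an adjusted p under 0.05. With the top 1000 peaks, TCR signal response genes were called for neither factor (1 of 20 for E2A and 2 of 20 for HEB). TCR complex and proximal signalling genes were then not called for E2A (3 of 19). Cd8a, Maf and Egr3 had no peak in any list.

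In CD73- cells 1 list was above chance for E2A, the pre-TCR and alpha-beta genes (7 of 17, 3.27 at random, adjusted permutation p = 0.539 over the 20 lists), and 8 for HEB, of which 1 had an adjusted p under 0.05. In CD73+ cells 1 list was above chance for E2A, the cytokine receptor and JAK-STAT genes (9 of 18, 4.50 at random, adjusted permutation p = 0.616), and 12 for HEB, of which 9 had an adjusted p under 0.05. The HEB lists there included TCR signal response (12 of 20, 3.46), pre-TCR and alpha-beta (12 of 17, 3.61), T lineage transcription factors (13 of 18, 5.74) and the IL-17 gamma-delta programme (9 of 15, 3.59). With strong peaks alone, 6 lists were above chance for CD73- E2A and 3 for CD73+ E2A.

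**Figure D3:**
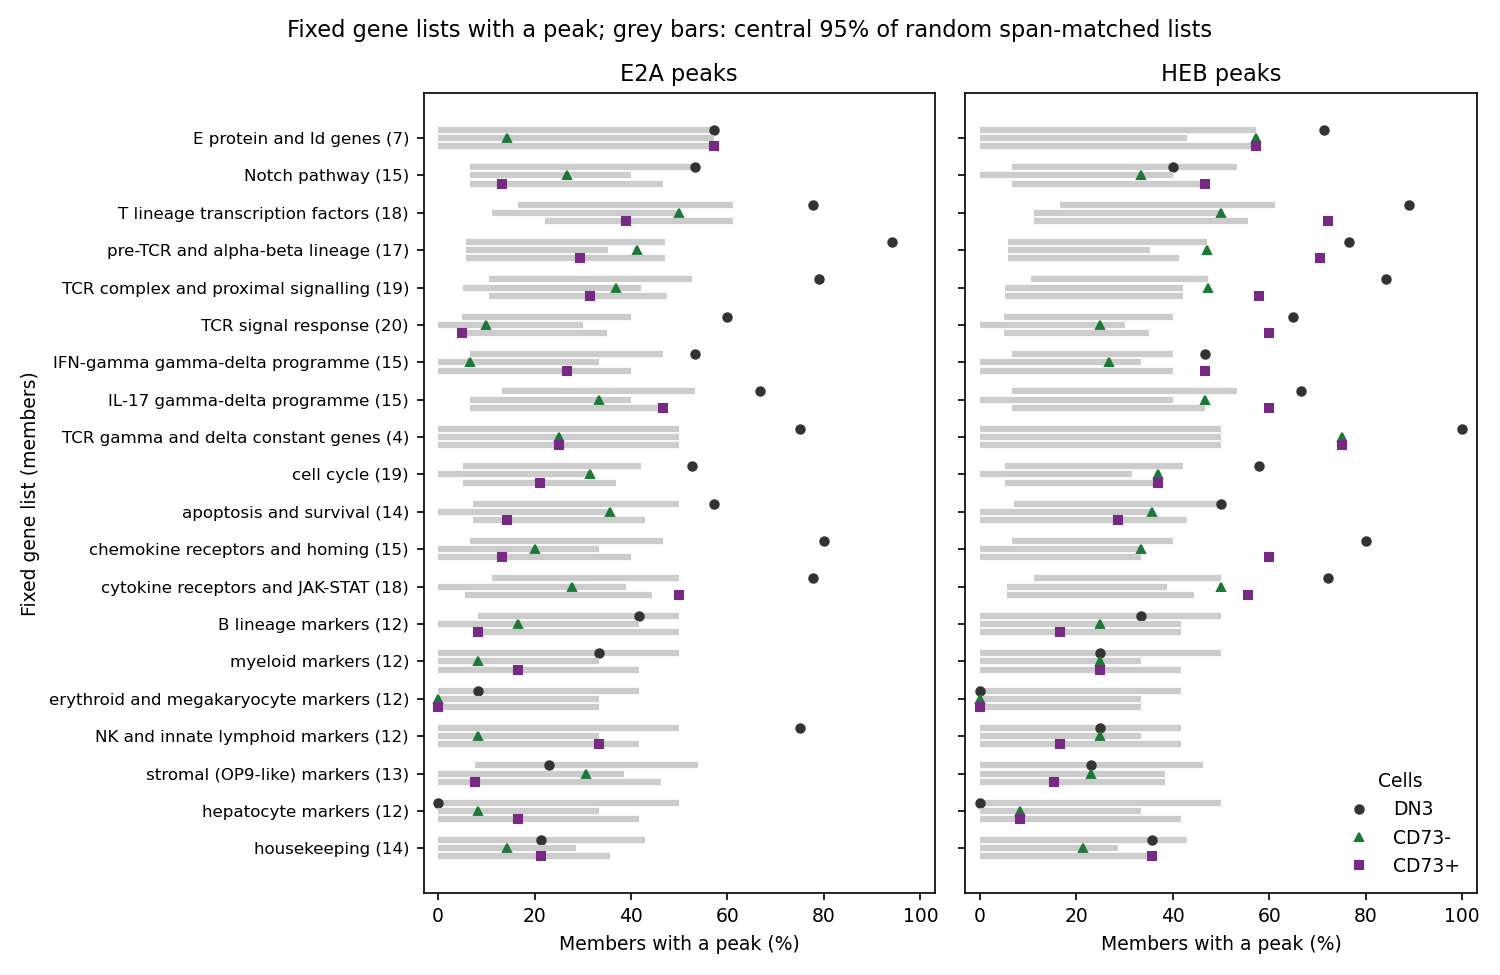
Members with a peak as a percent of each of the 20 fixed gene lists (y axis: list) for the 6 peak lists (x axis, percent of members), with grey bars for the central 95% of 10000 random lists. In DN3 cells E2A peaks lay at 16 of 17 pre-TCR and alpha-beta genes, against 5 in the CD73+ E2A list and 12 in the CD73+ HEB list.

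From DN3 to CD73- cells, TCR signal response genes with an E2A peak went from 12 to 2, chemokine receptor and homing genes from 12 to 3, pre-TCR and alpha-beta genes from 16 to 7, and cytokine receptor genes from 14 to 5. NK and innate lymphoid markers went from 9 to 1, and IFN-gamma gamma-delta programme genes from 8 to 1. From DN3 to CD73+ cells, TCR signal response genes went from 12 to 1, pre-TCR and alpha-beta genes from 16 to 5, chemokine receptor and homing genes from 12 to 2, and TCR complex and proximal signalling genes from 15 to 6. B lineage markers, a list whose highest-scoring member was the recombinase gene Rag1, went from 5 to 1. Against random lists matched on gene span, 7 and 10 lists were called, 6 and 4 of them with an adjusted p under 0.05. Of 8 settings, the fall to CD73- cells was called in 7 for chemokine receptor and for pre-TCR genes, in 4 for TCR signal response and in 3 for NK markers. The fall of TCR signal response to CD73+ cells was called in 6, and with the top 1000 peaks these genes went from 1 to 2 in CD73- cells. These lists were rich in E2A peaks in DN3 cells and so had more to lose. When random genes were also matched on having a DN3 peak, 0 lists were called for CD73- cells and 1 for CD73+ cells, TCR signal response (adjusted permutation p = 0.878). Over all genes, 33.8% of those with a DN3 E2A peak had one in CD73- cells and 36.6% in CD73+ cells. From CD73- to CD73+ cells, apoptosis and survival genes with an E2A peak went from 5 to 2 and stromal markers from 4 to 1, and neither call was kept under that matching. The CD73+ counts rest on the E2A and HEB labels of those cells, and in the CD73+ HEB list pre-TCR and alpha-beta genes numbered 12.

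For HEB, TCR signal response genes went from 13 to 5 and chemokine receptor and homing genes from 12 to 5 between DN3 and CD73- cells. These were among 5 lists called, of which 0 remained when random genes were matched on having a DN3 peak; over all genes 41.5% kept one. From DN3 to CD73+ cells no list was called against span-matched lists. With matching on a DN3 peak, the net counts of pre-TCR and alpha-beta genes and TCR signal response genes, each 13 then 12, fell less than at random (adjusted permutation p = 0.090 for each), with 2 and 1 genes gained and 3 and 2 lost. From CD73- to CD73+ cells TCR signal response genes rose from 5 to 12 (adjusted permutation p = 0.024), and chemokine receptor and homing genes went from 5 to 9 (adjusted permutation p = 0.552). With random genes matched on a CD73- peak, both rose (adjusted permutation p = 0.004 and 0.015). Of the 8 TCR signal response genes gained, 7 had a DN3 HEB peak, as had all 5 chemokine receptor and homing genes gained. Most of these genes were thus called again, and neither kind of random list was matched on DN3 peaks. Among TCR signal response genes, Nr4a1 had HEB peaks of 379, 135 and 751 at the 3 stages. Egr2, which acts in gamma-delta maturation, had 64.8, none and 206. Nfatc2 had 256, none and 138. These CD73+ counts rest on the same labels. The first rise was called in 5 of 8 settings and the second in 6. With peaks assigned to the nearest gene span or within 5 kb of a gene end, neither was, and with the top 1000 peaks the first was not. With strong peaks alone 7 lists were called, among them T lineage transcription factors (5 to 11) and pre-TCR and alpha-beta genes (5 to 11).

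**Figure D4:**
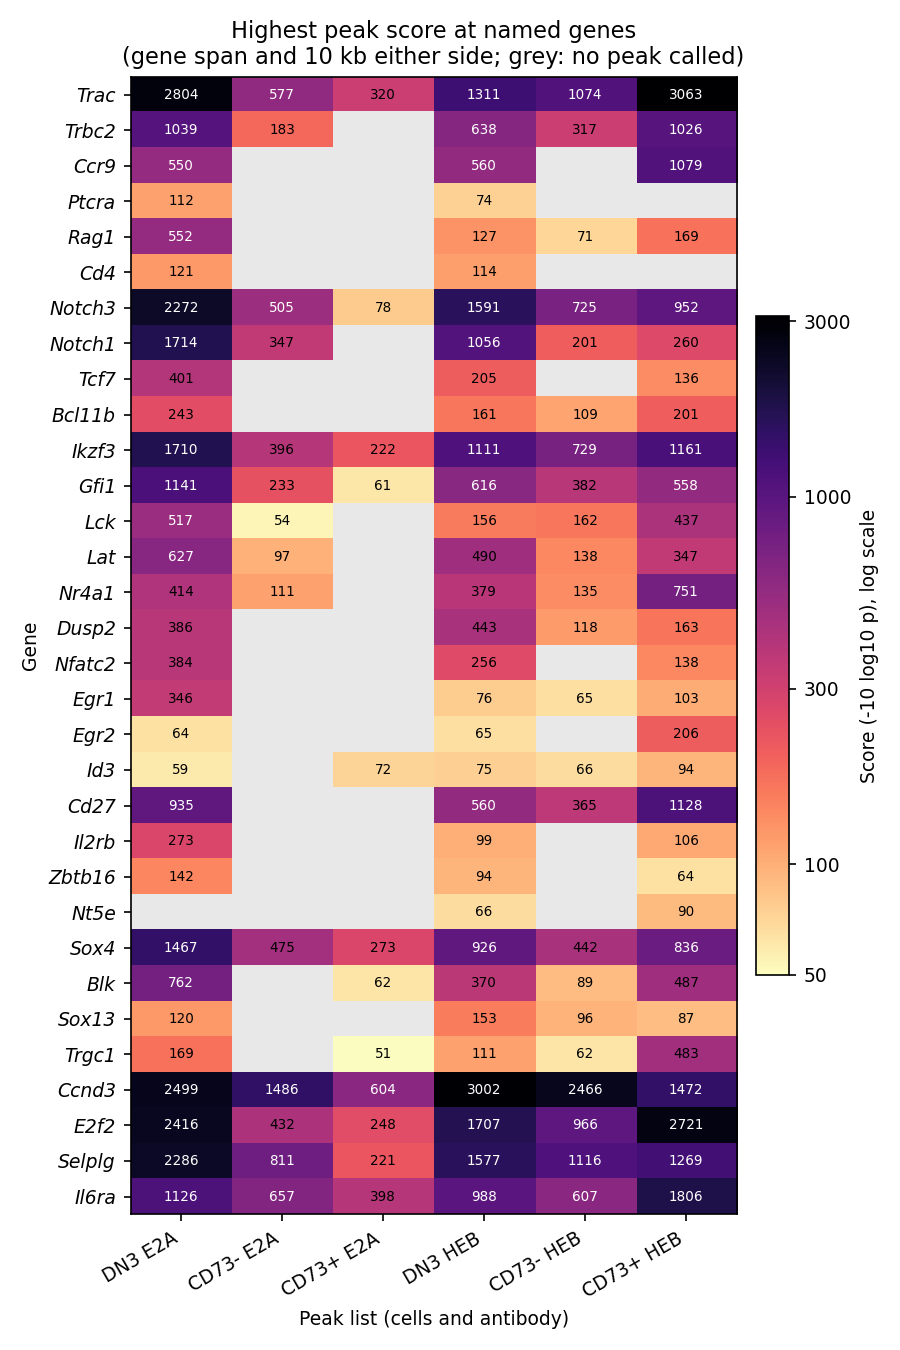
Highest peak score (-10 log10 p, colour) within 10 kb of each named gene (y axis) in each of the 6 peak lists (x axis), with empty cells where no peak was called. Scores rank peaks within a column only; Cd27 has a CD73+ HEB peak of 1128 and no CD73+ E2A peak.

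Of 15 IL-17 gamma-delta programme genes, 10, 5 and 7 had an E2A peak in DN3, CD73- and CD73+ cells and 10, 7 and 9 a HEB peak. Of 15 IFN-gamma programme genes the counts were 8, 1 and 4 for E2A and 7, 4 and 7 for HEB, and of 4 gamma and delta constant genes 3, 1 and 1 and 4, 3 and 3. Counted within 10 kb of gene spans, none of these 3 lists was above chance for CD73- or CD73+ E2A. Over 7 settings the IL-17 list was called in 3 for CD73- E2A and 2 for CD73+ E2A, and the constant genes in 1 for CD73+ E2A. For the list labelled CD73+ HEB all 3 were above chance. The adjusted permutation p was 0.010 for IL-17, 0.036 for IFN-gamma and 0.032 for the constant genes. Sox4, Blk and Etv5, which belong to the IL-17 gamma-delta programme, had DN3 E2A peaks of 1467, 762.3 and 376 and CD73+ HEB peaks of 836, 487 and 230.4. Zbtb16, which encodes the innate-like T cell factor PLZF, had DN3 E2A, DN3 HEB and CD73+ HEB peaks of 142, 94.3 and 63.9. The gamma chain constant gene Trgc1 had HEB peaks of 111, 62.1 and 483 in DN3, CD73- and CD73+ cells, and Trgc4 of 143, 86.5 and 251. Tbx21, which encodes the IFN-gamma regulator T-bet, had a single peak, CD73+ E2A at 54.1. Nt5e, which encodes CD73, had HEB peaks of 66.4 in DN3 and 89.6 in CD73+ cells and no E2A peak.

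Of 7 E protein and Id genes, 4, 1 and 4 had an E2A peak across the stages, above chance at none, and 5, 4 and 4 a HEB peak, above chance at all 3, with an adjusted p under 0.05 in DN3 cells only. Over 7 settings this list was called in 4 for DN3 E2A, 1 for CD73- E2A and 1 for CD73+ E2A. It was called in 4 for each HEB list, so the contrast in DN3 cells depends on the setting. Id3, an inhibitor induced by T cell receptor signals, had HEB peaks of 75.1, 66.0 and 94.3 and E2A peaks of 59.3, none and 71.8 across the stages. The CD73+ E2A peak stood at another position than the DN3 one. Id2 had E2A peaks of 141, none and 65.4, and Tcf12 had HEB peaks of 141, 56.6 and 242. Tcf3 had an E2A peak of 137 in DN3 cells only, and HEB peaks of 56.1 in CD73- and 91.0 in CD73+ cells. Gata3, a regulator of T cell commitment, had a DN3 HEB peak of 56.4 and E2A peaks of 61.3 in CD73- and 129 in CD73+ cells. Bcl11b, needed for T cell commitment, had a DN3 E2A peak of 243 and HEB peaks of 161, 109 and 201. The highest peak of a gene may stand at different positions in different lists, and neighbouring genes can share 1 peak.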

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

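The counts in this part were planned as the all-sequences alternative. Peaks on unplaced or random sequences, outside the 21 main chromosomes and so outside the comparisons, were present in every list, and this alone brought them here. They numbered 68 in the DN3 E2A list, 145 in the CD73- E2A list, 145 in the CD73+ E2A list, 44 in the DN3 HEB list, 151 in the CD73- HEB list and 131 in the CD73+ HEB list. No peak lay on the mitochondrial sequence. No explanation was tested for these peaks.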

How the results depend on the processing

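Chosen after seeing the data were the top 1000 peaks, the first list at a score of at least 100, gene-end placement classes, peaks overlapping another list, the nearest gene span, 5 kb of a gene end, matching on a first-stage peak, and gene-end shares. All 72 overlap values under alternatives stayed above random placement with an adjusted p under 0.05. Random placement gives few overlaps, so a shared input or shared background could also pass this test. They ran from 0.696%, at reciprocal overlap, which unequal widths limit, to 85.1%, and 29 differed more than 1.5 times from the main value. Of 12 gene-end shares under alternatives, 11 left the main interval. The alternatives were strong peaks alone and the wider distance of 2500 bp, and the wider distance can only raise a share.

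With a score of at least 100, peaks numbered 5011, 1093 and 1629 for E2A in DN3, CD73- and CD73+ cells and 3567, 1348 and 2458 for HEB; the stricter threshold itself removes peaks. Counts of fixed gene lists above chance differed over 1.5 times as follows. At that score they were 6 for CD73- E2A and 3 for CD73+ E2A, and at equal lengths, top 9407 peaks per list, 3 and 2. With the top 1000 peaks they were 7 for DN3 E2A, 6 for CD73- E2A, 7 for DN3 HEB and 5 for CD73- HEB. With peaks overlapping another list, CD73- E2A had 5. With the nearest gene span CD73- E2A had 5 and CD73+ E2A 4, and within 5 kb of a gene end 2 and 0.

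Counts of lists changed beyond chance differed likewise. At a score of at least 100 they were 5 for CD73- to CD73+ E2A, 2 for DN3 to CD73+ HEB and 7 for CD73- to CD73+ HEB. At equal lengths they were 4 for CD73- to CD73+ E2A and 1 for DN3 to CD73+ HEB. With the top 1000 peaks they were 3 and 4 for DN3 to CD73- and to CD73+ E2A, 6 for CD73- to CD73+ E2A, 2 and 6 for DN3 to CD73- and to CD73+ HEB, and 7 for CD73- to CD73+ HEB. With peaks overlapping another list they were 11 for DN3 to CD73- E2A, 3 and 2 for DN3 to CD73- and to CD73+ HEB, and 4 for CD73- to CD73+ HEB. With the nearest gene span they were 2 for DN3 to CD73+ HEB and 0 for CD73- to CD73+ HEB. Within 5 kb of a gene end they were 1 for CD73- to CD73+ E2A and 2 for DN3 to CD73+ HEB. With random genes matched on a peak in the first stage they were 0 for DN3 to CD73- E2A, 1 for DN3 to CD73+ E2A, 0 for DN3 to CD73- HEB, 2 for DN3 to CD73+ HEB and 8 for CD73- to CD73+ HEB. For CD73- to CD73+ E2A the count stayed at 2, but the lists were others, with more members. For changes from DN3 cells this matching removes the start with more peaks that the called lists shared. For changes from CD73- cells it leaves DN3 peaks unmatched. Otherwise, apart from the thresholds, the cause was not tested. No paired analysis was possible because each group has 1 pooled list, and no replicate could be left out. Not run for want of sequence or strand were E-box and other motif shares and windows, start site shares, placement by start site distance, nearest start site and 5 kb of a start site. Depth is unknown, and a site without a peak cannot be read as unoccupied.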

Other observations

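Tests chosen only after the result was seen were the overlap of new CD73+ E2A peaks with HEB, the ranking by DN3 E2A score, the share of unshared CD73+ HEB peaks with DN3 HEB, the tests of peak width, and the gene-end shares. Of 58451 regions merged over the 6 lists, 607 had a peak in all of them and 302 had a score of at least 100 in all. Among these was a region in Ccnd3, on chromosome 17 at 47541092 to 47543430, whose lowest score was 604. A region near Btg2, on chromosome 1 at 134066245 to 134068235, had a lowest score of 504, and the region near B4galt1 of 1053. Chosen after their values were seen, Dyrk1a, a kinase gene, had a region at chromosome 16, 94697808 to 94699631, with a lowest score of 1051, and Trim8 had 1 with a lowest score of 667. A score of 3100 in all 6 lists stood at 4 regions, on chromosome 14 at 19415281 to 19419885, on chromosome 17 at 39842814 to 39849284 and at a pair on chromosome 2. None lay within 100 kb of a protein-coding gene, and genes of other kinds were not searched. They have the look of high-background regions, and they were kept, since no list of such regions was used.

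Counted within 10 kb of gene spans, marker lists of B, myeloid, erythroid, stromal and liver cells were above chance in no peak list, while NK and innate lymphoid markers were for DN3 E2A (9 of 12, 2.81 at random). Assigned to the nearest gene span, stromal markers were called for CD73- E2A and DN3 HEB, and within 5 kb of a gene end B lineage markers were for CD73- HEB. The NK call for DN3 E2A was made in 4 of 7 settings. Over these settings housekeeping genes were called in 2 for CD73- E2A, 1 for CD73+ E2A, 1 for CD73- HEB and 2 for CD73+ HEB. Erythroid and megakaryocyte markers had 1 E2A peak, at Slc4a1 in DN3 cells (76.9), and no HEB peak, and liver markers had none in DN3 cells. Of 13 stromal markers, E2A peaks lay at 3, 4 and 1 in DN3, CD73- and CD73+ cells, of which Thy1, which T cells also express, had the highest, 576 in DN3 cells. Of 12 myeloid markers they lay at 4, 1 and 2, including Itgam, an integrin gene, at 1184, 366 and 141. Il22, a cytokine gene of innate lymphoid and T cells, had E2A peaks of 1866, 109 and 291 and HEB peaks of 971, 247 and 951. Ebf1, the B lineage regulator, had DN3 peaks of 173 for E2A and 85.5 for HEB and none later. Of the HEB regions with peaks in both sorted populations and none in DN3 cells, 4 of the 5 highest lay in a 30.2 kb window on chromosome 6, 47654772 to 47684946. That window held 21 and 24 HEB peaks in CD73- and CD73+ cells and 0 in DN3 cells, but 4, 19 and 35 E2A peaks across the stages. The 4 DN3 E2A peaks covered 30132 bp of it, the later ones 26538 bp and 17326 bp, so the rising count is not a gain in covered length. Whether high background lies in this window was not tested, so its HEB regions cannot be read as gained sites.

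The CD73+ E2A list was the longest but held few strong peaks. Of its 19598 peaks without a DN3 or CD73- peak, 1.46% (95% interval 1.31% to 1.64%) overlapped a CD73+ HEB peak. Of the 815 strong ones, 2.58% did so. Sites newly called for both factors thus made up little of the list. The bound set for joint new sites could not be reached, since 1566 of all 23205 peaks overlapped a CD73+ HEB peak. Joint occupation of new sites therefore stays open. The 18517 CD73+ E2A peaks that scored under 100 and met no other list were also examined. They lay within 1 kb of a gene end 0.240 times as often as random positions (0.202 to 0.284). An even background would give about 1, so an even spread is argued against, while background calls that avoid gene ends cannot be told apart from E2A sites away from genes, since both allow this value. A difference in depth was not tested and stays open.

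Strong CD73+ HEB peaks overlapped DN3 E2A peaks more often than CD73+ E2A peaks. An exchange of the E2A and HEB labels in the CD73+ cells could give this, and the CD73+ HEB list did overlap strong DN3 peaks of E2A alone (25.8% of 1130) more than those of HEB alone (20.5% of 533), odds ratio 1.35 (1.05 to 1.73). The CD73+ E2A list had an odds ratio of 0.145 (0.103 to 0.202), but both CD73- lists were also below 1, at 0.278 (0.208 to 0.372) for E2A and 0.259 (0.199 to 0.336) for HEB, so the ratio did not separate the antibodies there and an exchange stays open, not shown. Lower sensitivity of the CD73+ E2A list cannot be told apart from other explanations: the DN3 E2A score ranked shared above unshared peaks with an area under the curve of 0.665 (0.640 to 0.689, n = 2094), between the bounds set for and against it. Of the 1385 strong CD73+ HEB peaks on a DN3 E2A peak but no CD73+ E2A peak, 83.2% (81.1% to 85.1%) overlapped a DN3 HEB peak. If the labels hold, HEB was thus already called at most of these sites in DN3 cells. As 90.3% of DN3 E2A peaks scoring 200 to 400 overlapped a DN3 HEB peak anyway, this share cannot decide on a move of HEB. Loss of E2A from shared sites was not tested and stays open.

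Peaks of the CD73- and CD73+ lists were narrower than DN3 peaks. A larger share of weak peaks is argued against, since among E2A peaks scoring 200 to 400 the median width in DN3 cells was 4.60 times that in CD73+ cells (3.39 to 6.62), and in the other pairs of lists 1.88 to 2.68 times. Among the top 1000 peaks of each list, which needs no score matched across lists, the DN3 median was 2.42 to 10.7 times the other. The narrowest DN3 peaks, at the first percentile of width, were 4.42 times as wide as the widest such value among the other 4 lists, which restates the pattern, so a different fragment length or peak model cannot be told apart from other explanations. No biological explanation was tested.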
